A study of Mus musculus with 8 samples.

How the data were processed

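Gene expression was measured by RNA sequencing in the brachiocephalic artery, the branch of the aortic arch in which plaques form in ApoE-deficient mice. Per the labels' protocols, the mice received a high-fat diet from 12 weeks of age, and plaques formed on it. 4 samples came from mice injected with a blocking antibody against Dll1 (clone HMD1-5), a ligand of the Notch receptors. The other 4 samples came from mice given non-immune IgG, which served as controls. Both were given into the peritoneum at 250 micrograms, 2 times per week. RNA was extracted with TRIZOL, 100 ng per sample was depleted of ribosomal RNA, and libraries were made with a kit that keeps the strand. The labels do not say whether the samples are separate animals, so p-values measure the spread between these samples, which may be technical in part.

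The table deposited by the authors gives TPM, a length-adjusted share of transcripts, for 49585 mouse genes in 8 libraries, with 1 column per library and no pooling. Each column sums to 1000000 over all listed genes, non-coding genes included, per the file headers and the values. The aligner, the counting tool, their versions and the annotation release are not given in the sources used here. Per the submitters' processing notes the build was hg19, a human build, while the deposited table lists mouse Ensembl identifiers. For that reason no genome coordinates are given. Of the listed identifiers, 49326 were in GENCODE M21, the mouse annotation used here for gene types and exon lengths, and 259 were not. Symbols are those of the deposited table.

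The column names give the group and the number 045 or 076, whose meaning is not given in the sources used here. They do not say which numbered sample of the labels each column holds, so a column was treated as a replicate of its group. The libraries of each number are called a set here. Set 045 held IgG libraries C1IA and C2IA and antibody libraries D1IA and D2IA. Set 076 held IgG libraries G1IA and G2IA and another pair of antibody libraries named D1IA and D2IA.

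TPM keeps no depth by itself, but the values times exon length fell on whole multiples of 1 step per library, taken as 1 read, within a relative tolerance of 1e-05. All 25386 genes above 0 in any library gave whole reads (100%), 19704 with the M21 exon length and 5682 with a length derived from the steps themselves. The derivation was checked on 12509 genes with a known length and at least 20 reads. It gave the known length for 99.6% of them, and that length or a divisor of it for 100%. Recovered reads numbered 11062677 to 13816416 per library, of which 663099 to 8070921 lay on nuclear protein-coding genes, so counting error was larger in the libraries of set 045. Recovered reads served for depth, for the immunoglobulin share and for 1 alternative test.

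The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended and robust empirical Bayes step, for 11468 genes with a mean of at least 1 TPM over the 8 libraries. It compared 4 antibody libraries with 4 IgG libraries, two-sided, with no other term. p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A log2 fold change is antibody minus IgG on the log2(TPM + 1) scale, which understates the change of low genes. The residual degrees of freedom were 6. The prior degrees of freedom were estimated as infinite, so the main test used a variance shared by genes of like level. A gene more variable than others of its level thus gets a smaller p than its own spread would give. Of 37 gene lists for Notch signalling, plaque cell types, matrix, inflammation, lipid handling and neighbouring tissues, 36 had at least 4 tested members. These were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list stands apart from the other genes. Camera with an estimated correlation and fry were run beside it. Levels of libraries of different sets were also compared after rescaling TPM to the total of nuclear protein-coding genes, called the protein-coding scale. On this scale 18170 genes were tested. The difference between the sets was tested with limma, with treatment as a further term, and the treatment effect was compared between the sets by an interaction term.

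The grouping, the tests, the gene lists, the rule for named genes and the first of the groups of alternatives were set before the data were examined. By that rule the text names genes past the threshold whose groups do not overlap, then the genes of smallest p up to 10 per direction. It also names Dll1, the 4 Notch receptors, Dll4, Jag1, Jag2, Hes1, Hey1, Hey2, Heyl and Nrarp, and up to 4 members of smallest p in each list described. Genes without a symbol and predicted gene models are counted but not named. Genes named outside the rule, because of their values, are Igkc, Tnfrsf17, Slpi, Ms4a1, Cd79a, Pth, Acta2, Apoe, Rag1, Rn7s1, Gm22042 and the label checks Xist and Ddx3y. The lists described in detail were chosen after their results were seen.

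The alternatives set beforehand were pseudocounts of 0.1 and 5 TPM, no filter, a filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization, plain empirical Bayes, array weights, the set as a term and leaving out each library. Those planned for a table of raw counts were not run, since the deposited unit is TPM. Added after seeing the data were the protein-coding scale without and with the set as a term, and each set alone on that scale. A fit on that scale with the set as a term, but without the 2 libraries that hold Xist reads, was added too. So were tests of the skeletal muscle list without D1IA of set 076 with an estimated correlation and on the protein-coding scale. Also added was limma-voom on the recovered reads with the set as a term, for 14354 genes with at least 10 reads in at least 4 libraries.

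The fits were tested on simulated data. Reads were drawn for the real genes from the mean shares of each set and the sizes of the real libraries. All genes were given the median dispersion of 0.0815. Between the treatment groups 200 genes were changed, 100 by 4-fold and 100 by 16-fold. A list of 20 changed genes and 20 unchanged lists were tested with camera. With the preset correlation the changed list was called at adjusted p = 2.3e-49 and 0 of the 20 unchanged lists were called. With the estimated correlation the changed list was not called (adjusted p = 0.20). The draws held no differences in composition between libraries of a set, which can move the genes of a list together. In the main fit the estimated correlation of the real lists was 0.685 (nerve) to 0.995 (oxidative phosphorylation), against the preset 0.01. That fit has no term for the set, so the difference between the sets raises these values, and they do not measure composition alone. Because the draws held no differences in composition, the 0 unchanged lists called do not show that p-values with the preset correlation hold for the real lists.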

Results

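Plaque-bearing brachiocephalic arteries of ApoE-deficient mice were profiled to examine what blocking Dll1 does to gene expression there. The comparison was between 4 samples given non-immune IgG and 4 given the Dll1 antibody. The deposited table listed 49585 genes in TPM. Recovered reads totalled 11062677 in C1IA, 13281155 in C2IA, 12588369 in D1IA and 12218566 in D2IA of set 045. In set 076 they totalled 11670905 in G1IA, 13816416 in G2IA, 13705807 in D1IA and 12115182 in D2IA.

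The strongest difference among the libraries was between the sets, each of which held 2 IgG and 2 antibody libraries. Rn7s1, a gene for 7SL RNA, the RNA of the signal recognition particle, took 62.7% to 72.8% of all TPM in set 045 and 31.4% to 43.0% in set 076. Nuclear protein-coding genes took 0.848% to 3.10% of TPM in set 045 and 21.2% to 24.2% in set 076. Acta2, the actin of smooth muscle, lay at 3.53 to 9.35 TPM in set 045 and at 402 to 510 TPM in set 076. Apoe, the gene in which the mice are deficient, was listed at 0.287 to 0.862 TPM in set 045 and 2.45 to 8.03 TPM in set 076.

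Between the sets, 10888 of 11468 genes were higher in set 076 and 10 were lower in TPM (limma, adjusted p under 0.05), with a median difference of 2.17 on the log2 scale. On the protein-coding scale 486 of 18170 genes were higher and 1243 lower in set 076, and 26.9% of genes lay more than 2-fold apart. On that scale the contractile smooth muscle list lay a median of 2.93-fold higher in set 076, with 15 of 25 members called higher. The heart muscle list lay 8.07-fold higher, with 5 of 13 members called, and the brown fat list 4.44-fold higher, with 4 of 14 called. Other lists lay lower in set 076. The nerve list lay at 0.229 times its level in set 045 (1 of 19 members called lower) and sterol synthesis at 0.334 times (0 of 18). Mitochondrially encoded genes lay at 0.409 times (4 of 13) and Notch components at 0.754 times (8 of 28). The first principal component held 92.4% of the variance in TPM and separated the sets. On the protein-coding scale it held 42.9% and did not, since D1IA of set 045 lay at 33.2, above D2IA of set 076 at -4.26. Across genes, which are not independent replicates, log2 TPM of IgG and antibody libraries of 1 set correlated at 0.846 to 0.943. Libraries of 1 group in different sets correlated at 0.660 to 0.820 and libraries of different group and set at 0.677 to 0.888. These ranges overlapped on the protein-coding scale, at 0.772 to 0.950, 0.744 to 0.860 and 0.749 to 0.90. The 663099 to 2729071 protein-coding reads of set 045, against 7422343 to 8070921 in set 076, leave low genes less precisely measured in set 045. Xist, which is transcribed from an inactive X chromosome, lay at 4.46 TPM in C1IA and 5.44 TPM in D2IA of set 045. It lay at 0.0342 TPM or less in the other 6 libraries. The Y-linked gene Ddx3y was listed at 0 in C1IA and D2IA of set 045 alone. The 2 libraries of each group in set 045 thus differed in these genes, which copies of 1 sample would not.

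**Figure D1:**
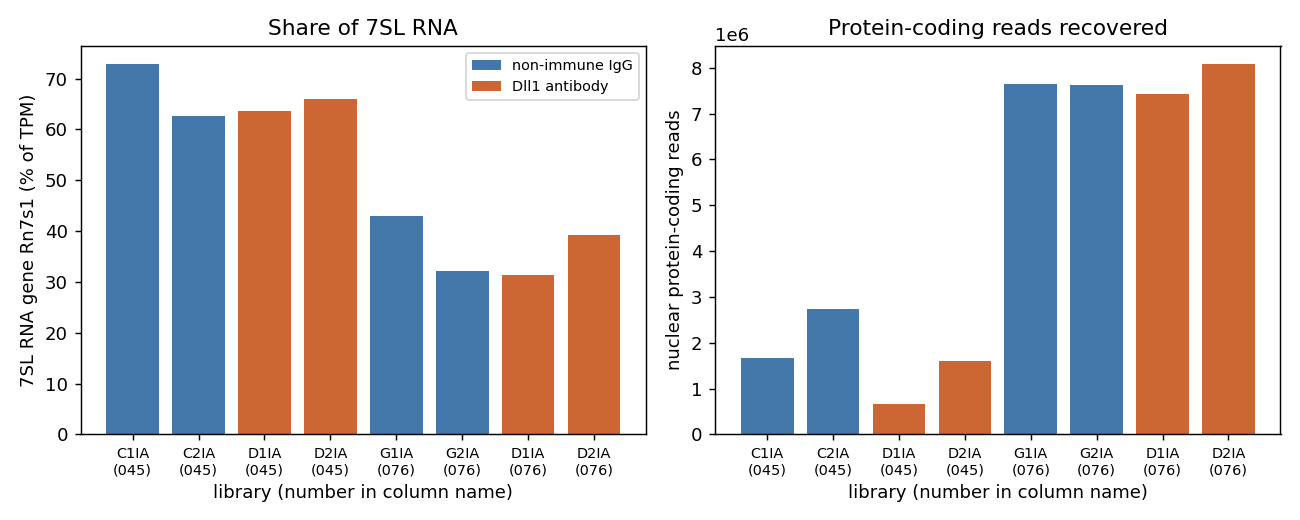
Share of TPM taken by the 7SL RNA gene Rn7s1 (left, percent) and reads recovered for nuclear protein-coding genes (right) in each of the 8 libraries, with non-immune IgG in blue and Dll1 antibody in orange. The 4 libraries of set 045 lie at 62.7% to 72.8% and 663099 to 2729071 reads, and the 4 of set 076 at 31.4% to 43.0% and 7422343 to 8070921 reads.

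Dll1 (ENSMUSG00000014773), whose protein the antibody binds, was detected in every library. The binding of its protein need not change its transcript, so its level checks no label. In set 045 Dll1 lay at 0.282 and 0.291 TPM with IgG and at 0.168 and 0.440 TPM with the antibody. In set 076 it lay at 3.72 and 2.70 TPM with IgG and at 1.66 and 2.87 TPM with the antibody. The means were 1.75 ± 1.74 TPM with IgG and 1.28 ± 1.24 TPM with the antibody (SD, n = 4 each). Its log2 fold change of -0.19 (SE 0.70) was smaller than the spread between replicates (limma adjusted p = 1.00). It was 0.78 in set 045 and -0.56 in set 076 on the protein-coding scale, so its direction differed between the sets.

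None of the Notch ligands, receptors and target genes followed here passed the threshold. The 4 receptors had log2 fold changes from -0.27 for Notch3 to 0.09 for Notch4, against a median over all genes of -0.17. The ligands Dll4, Jag1 and Jag2 had log2 fold changes of 0.04, -0.23 and -0.12. Among target genes transcribed when Notch is active, Hey1, Hey2, Heyl and Nrarp had 0.08, -0.30, -0.27 and 0.05. Hes1, a repressor that Notch switches on directly, had -0.43 (SE 0.82, adjusted p = 1.00), with 4.75 and 5.03 TPM with IgG and 3.57 and 3.89 TPM with the antibody in set 076. In set 045 Hes1 lay at 0.302 and 0.989 TPM with IgG and at 0.109 and 0.106 TPM with the antibody. With the protein-coding scale and the set as a term, its log2 fold change was -0.89 (SE 0.33, limma adjusted p = 1.00). Of 25 tested Notch components, 2 were higher and 23 lower (median log2 fold change -0.18, camera adjusted p = 0.979). With the protein-coding scale and the set as a term 13 were higher and 15 lower (median -0.01, adjusted p = 0.592). Psenen, a subunit of gamma-secretase, and Itch, a ubiquitin ligase, had the smallest p among them, with log2 fold changes of -0.51 and -0.32. Of 17 tested Notch target genes, 3 were higher and 14 lower (median -0.21, adjusted p = 0.979), against 10 higher and 11 lower on the protein-coding scale with the set as a term (median -0.04, adjusted p = 0.868). In the main fit without the set both lists had adjusted p = 0.999 with an estimated correlation, and 0 members of either passed when adjusted over the list alone. That fit also called 0 of the changed genes in simulated libraries, so these counts of 0 limit little. The signs of Dll1, Notch1, Notch2 and Jag1 were not the same under all scalings.

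**Figure D2:**
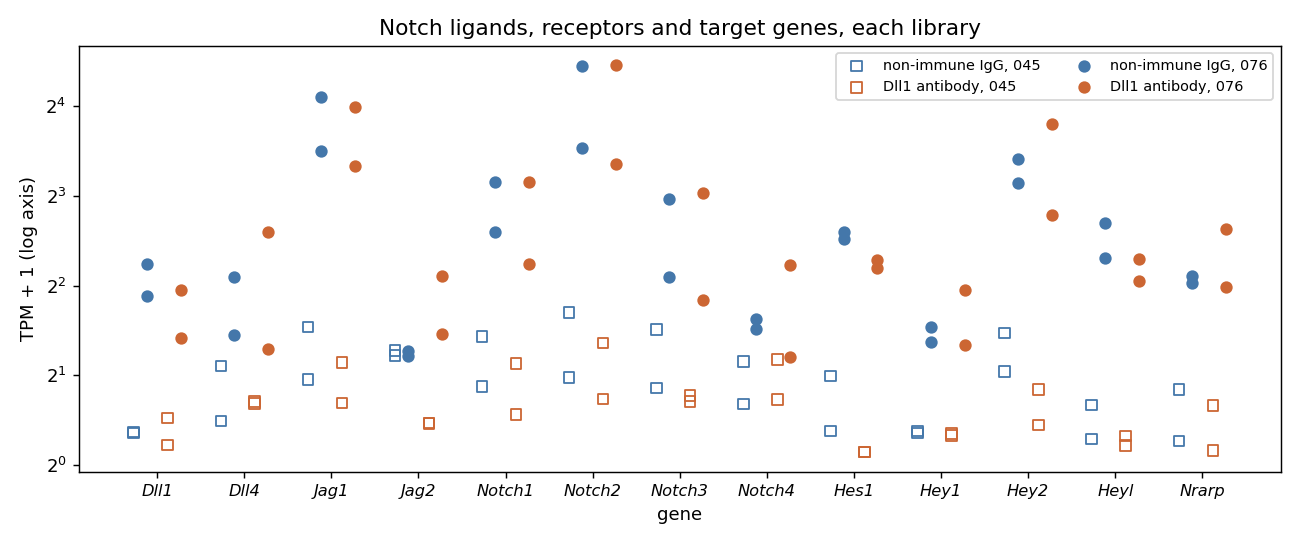
TPM + 1 (log axis, base 2) of 13 Notch ligands, receptors and target genes, with 1 point per library, IgG in blue and Dll1 antibody in orange, set 045 as open squares and set 076 as filled circles. Most genes lie higher in set 076 than in set 045 in both groups, as for Notch2 at 9.18 to 20.9 TPM against 0.665 to 2.26 TPM, and IgG and antibody points of 1 set overlap for most genes.

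Over all genes, the treatment left no gene past the threshold. limma called 0 genes higher and 0 lower with the antibody among 11468, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 59 genes, 15 higher and 44 lower, where 573 would be expected by chance. With the set as a term 1 gene was lower, the predicted gene model Gm22042 (log2 fold change -1.24, SE 0.21, limma adjusted p = 0.0444). In that fit 47 genes had an unadjusted p under 0.05, against 573 expected by chance. With both the protein-coding scale and the set as a term 0 of 18170 genes passed. There 278 had an unadjusted p under 0.05, against 908 expected. limma-voom on the recovered reads with the set as a term called 0 of 14354, with 151 at an unadjusted p under 0.05 against 718 expected. The counts with the set as a term thus also lay below those expected by chance. In simulated libraries of this comparison with the same difference between sets, the limma test without the set among 11524 genes called 0 of 94 genes changed 4-fold and 0 of 90 changed 16-fold. With the set as a term it called 93.6% and 84.4% of them, and 3 unchanged genes. The protein-coding scale with the set as a term called 96% and 100% of 100 genes each among 18042, with 8 unchanged genes called. limma-voom called 100% of 95 genes at each fold size among 14547, with 12 unchanged genes called. A count of 0 without the set as a term therefore does not limit changes of these sizes. The simulation gave all genes 1 dispersion around the mean of each set, so differences in composition between libraries of a set were left out. The shares called with the set as a term may thus be too high for the real libraries, and a count of 0 there does not exclude such changes either.

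Immunoglobulin genes were the 10 genes of smallest p among those lower with the antibody, and the gap lay mostly in set 076. Ighm (ENSMUSG00000076617), the constant part of the IgM heavy chain, lay at 724 and 696 TPM in the IgG libraries of set 076 and at 40.2 and 83.9 TPM in its antibody libraries. Igkc, the constant part of the kappa light chain, lay at 962 and 1756 TPM against 63.4 and 119 TPM. Jchain, which joins IgM and IgA into polymers, lay at 161 and 223 TPM against 5.43 and 14.3 TPM. Mzb1, a chaperone of antibody-secreting cells, lay at 9.42 and 6.79 TPM against 0.580 and 0.973 TPM. The variable segments Ighv2-9-1, Igkv1-117, Igkv1-110, Igkv1-135, Igkv3-4, Igkv9-124, Igkv4-53, Ighv1-82 and Iglv2 and the lambda constant gene Iglc3 lay at 4.71 to 270 TPM in the IgG libraries of set 076 and at 0 to 1.56 TPM in its antibody libraries.

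IgG, on the protein-coding scale, exceeded antibody in set 076 by 12.2-fold for Ighm, 16.1-fold for Igkc, 21.1-fold for Jchain and 11.0-fold for Mzb1. In set 045 the same ratio was 2.49 for Ighm, 2.50 for Igkc and 5.03 for Jchain, but it rested on IgG library C1IA. On this scale Ighm lay at 559 in C1IA and 94.5 in C2IA against 160 and 102 with the antibody, Igkc at 711 and 47.9 against 225 and 78.2, and Jchain at 84.2 and 2.81 against 12.4 and 4.86. For each of these genes C2IA lay below both antibody libraries of the set. Over both sets Ighm had 358 ± 407 TPM with IgG and 31.8 ± 39.2 TPM with the antibody (SD, n = 4 each), a log2 fold change of -2.45 (SE 1.73, limma adjusted p = 1.00). Leaving out 1 library moved it from -3.82 (without C2IA) to -1.31 (without G1IA), and that of Igkc from -4.21 (without C2IA) to -1.05 (without G2IA). Igha, the constant part of IgA, went the other way, at 23.8 TPM in antibody library D2IA of set 076 and at 0.952 TPM or less in the other 7 libraries. Its level on the protein-coding scale was 98.4 in that library, 46.9 in antibody library D1IA of set 045 and 15.3 or less in the other 6. The B cell surface genes Ms4a1 and Cd79a were near the floor in all libraries, with at most 0.638 TPM and 1.14 TPM. Other genes were lower with the immunoglobulin genes in set 076. Slpi, a secreted protease inhibitor, lay at 87.5 and 73.4 on the protein-coding scale with IgG and at 3.79 and 13.9 with the antibody, and Ccl21a, a chemokine of lymphatic vessels, at 106 and 90.8 against 7.02 and 69.5. The lymphatic endothelial list had a median log2 fold change of -0.43 in set 076 (camera adjusted p = 0.0064, but 0.877 with an estimated correlation) and -0.15 in set 045 (adjusted p = 0.581). Its mean log2 value in set 076 was low in D1IA alone, at 3.80, against 4.89 in D2IA and 5.10 and 4.77 with IgG. Over all 8 libraries it was not called (adjusted p = 0.224, and 0.999 with an estimated correlation), but was called lower by limma-voom with the set as a term (adjusted p = 0.0228, and 0.613 with an estimated correlation).

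The B cell and plasma cell list fell with the antibody by the preset correlation: 5 of 6 tested members were lower and 1 higher (median log2 fold change -1.83, camera adjusted p = 9.2e-07). With an estimated correlation its adjusted p was 0.433, and 0 members passed in the main fit without the set when adjusted over the list alone. The protein-coding scale kept 18 members in the test, and with the set as a term 14 were lower and 4 higher (median -0.52, adjusted p = 9.2e-04, but 0.664 with an estimated correlation). Over these 18 members the median was -0.84 in set 076 (adjusted p = 3.6e-11) and -0.50 in set 045 (adjusted p = 0.512). With an estimated correlation 0 lists were called in either set alone, which holds for every value within a set given here. The smallest adjusted p by camera was 0.877 in set 076 and 0.480 in set 045. With 2 libraries against 2 this test has little power. Even with 8 libraries camera with an estimated correlation missed the simulated changed list (adjusted p = 0.20). These counts of 0 therefore exclude little. The difference between the sets had an adjusted p of 0.0369 with the preset and 0.673 with an estimated correlation. In set 076 alone, limma on 18170 genes called 3 genes lower and 0 higher, with 296 at an unadjusted p under 0.05. They were Igkv1-117 (log2 fold change -8.06, adjusted p = 0.0060), Ighv2-9-1 (-9.01, adjusted p = 0.013) and Igkv1-110 (-7.53, adjusted p = 0.015), and each was higher in both IgG libraries than in both antibody libraries. Reads of immunoglobulin constant genes per 1000000 protein-coding reads were 2602 and 3404 with IgG and 183 and 327 with the antibody in set 076. In set 045 they were 382 in C1IA and 61.6 in C2IA with IgG and 185 and 68.2 with the antibody, so only C1IA lay above the antibody libraries. The means were 1613 ± 1644 and 191 ± 106 (SD, n = 4 each), a log2 difference of -2.03. The difference was not past the threshold in a two-sided exact permutation test over all 70 assignments (p = 0.229), or over the 36 assignments within sets (exact p = 0.167, where 0.0556 is the smallest possible). Variable segments form a family of similar genes, so the split of reads among them is uncertain. The call of the list was lost with array weights (adjusted p = 0.0898). On the protein-coding scale with the set as a term it was lost without the 2 libraries with Xist reads (adjusted p = 0.178, against 9.2e-04 with all 8). The range over all alternatives was 1.2e-23 to 0.998.

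**Figure D3:**
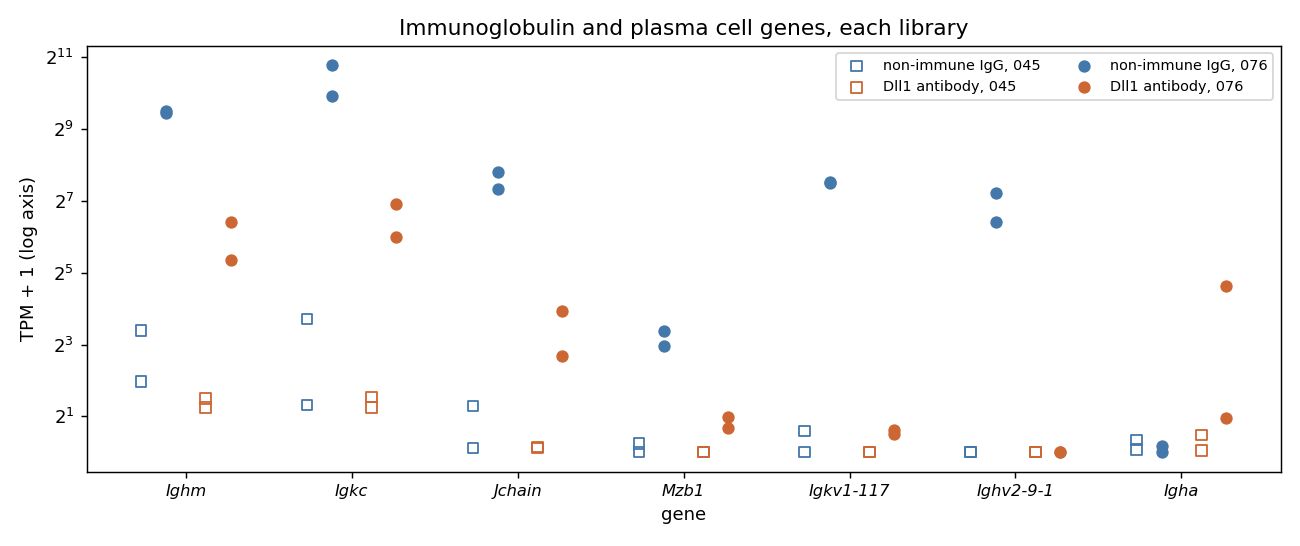
TPM + 1 (log axis, base 2) of 7 immunoglobulin and plasma cell genes, with 1 point per library, IgG in blue and Dll1 antibody in orange, set 045 as open squares and set 076 as filled circles. In set 076 the IgG libraries lie above the antibody libraries for every gene but Igha, as for Ighm at 724 and 696 TPM against 40.2 and 83.9 TPM.

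Genes of fast skeletal muscle led those higher with the antibody, and they did so in set 076. Pvalb, a calcium buffer of fast fibres, lay at 124 TPM in D1IA and 7.61 TPM in D2IA, against 0.999 and 0 TPM in the IgG libraries of the set, and was listed at 0 in all 4 libraries of set 045. Mylpf, a myosin light chain, lay at 146 and 7.57 TPM against 2.06 and 0.335 TPM. Tnni2, a fast troponin, lay at 65.7 and 6.18 TPM against 0.833 and 0.178 TPM. Myh1, Myh4, Myoz1, Myot, Tnnc2 and Mybpc1 had log2 fold changes from 1.22 to 1.95 over both sets. All 19 tested members of the skeletal muscle list were higher, 11 of them at an unadjusted p under 0.05, with a median log2 fold change of 1.69 (camera adjusted p = 2.2e-200). The list was the only 1 still called with an estimated correlation (adjusted p = 0.0082). In the same fit without the set, 0 members passed when adjusted over the list alone. The median was 4.30 in set 076 (adjusted p = 4.5e-19) and -0.65 in set 045 (adjusted p = 0.139). The difference between the sets had an adjusted p of 3.0e-11 with the preset and 0.584 with an estimated correlation. Over all alternatives its adjusted p ranged from 2.0e-251 to 0.998. Without D1IA of set 076 the list was still called with the preset correlation (14 members tested, adjusted p = 6.8e-34), but its median was 0.49. The median of all genes was -0.48 in that fit, against -0.17 with all 8 libraries. The list was not called without D1IA with an estimated correlation (adjusted p = 0.534), or on the protein-coding scale with the set as a term (median 0.23, adjusted p = 0.0624, and 0.877 with an estimated correlation). Pvalb, Mylpf, Tnni2, Myh1 and Myh4 had log2 fold changes of 0.79, 0.45, 0.69, 0.69 and 0.60 without D1IA, against 2.27, 1.98, 1.95, 1.78 and 1.95 with it. With all 8 libraries on the protein-coding scale and the set as a term, the list had an adjusted p of 0.664 with an estimated correlation. D1IA of set 076, the library with the most muscle signal, stood apart for genes of other tissues as well. It held Pth, parathyroid hormone, at 932 on the protein-coding scale against 17.2 or less in the other 7 libraries, and Col10a1 at 130 against 37.6 or less. The mean log2 values of the thymocyte and red cell lists on that scale were also highest in it, at 4.88 and 8.72, against at most 3.92 and 8.39 elsewhere.

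Genes of T cells and thymocytes followed single libraries of both groups. Dntt, the polymerase that adds bases when antigen receptors are joined, lay at 5.96 and 0.0837 TPM in IgG libraries G1IA and G2IA and at 11.6 and 1.97 TPM in antibody libraries D1IA and D2IA of set 076. Cd8b1, a coreceptor chain, lay at 4.70 and 0.0601 TPM against 10.4 and 1.93 TPM. Trbc1, a constant gene of the T cell receptor, lay at 11.1 and 0.595 TPM against 19.9 and 4.85 TPM. The T cell list rose, with 7 of 9 tested members higher (median log2 fold change 0.47, camera adjusted p = 2.1e-10, but 0.433 with an estimated correlation). The thymocyte list rose, with 5 of 7 higher (median 0.47, adjusted p = 1.0e-08, but 0.433 with an estimated correlation). With the protein-coding scale and the set as a term, 11 of 20 T cell members were higher and 9 lower (median 0.23, adjusted p = 0.0236), and 8 of 12 thymocyte members higher and 4 lower (median 0.53, adjusted p = 0.0162), each with 0.710 with an estimated correlation. The medians on that scale were 0.46 and 1.16 in set 076 and -0.01 and -0.10 in set 045. Without D1IA of set 076 the adjusted p was 0.59 for T cells and 0.83 for thymocytes, and without G2IA it was 0.169 for T cells. The ranges over all alternatives were 3.4e-28 to 0.998 and 2.0e-24 to 0.998.

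Genes of red cells, mast cells and neutrophils were higher with the antibody by the preset correlation. For red cells, all 7 tested members were higher (median log2 fold change 0.55, camera adjusted p = 1.8e-07, but 0.472 with an estimated correlation). The red cell medians were 0.94 in set 076 (adjusted p = 7.5e-06) and 1.37 in set 045 (adjusted p = 0.0040). In set 045 the mean log2 value of the list was 8.39 in D1IA, the library with the fewest protein-coding reads, and 7.11 in D2IA, against 7.03 and 6.30 with IgG. Hba-a1, an alpha globin gene with a near-identical copy, lay at 1746 and 507 TPM with the antibody against 575 and 379 TPM with IgG in set 076, and at 33.7 and 19.6 TPM against 19.4 and 13.2 TPM in set 045. Slc4a1, the anion exchanger of red cells, lay at 3.15 and 2.09 TPM against 1.25 and 0.783 TPM in set 076. For mast cells, 6 of 7 members were higher (median 0.29, adjusted p = 0.0021, but 0.999 with an estimated correlation), with medians of 0.61 in set 076 (adjusted p = 0.0015) and 0.59 in set 045 (adjusted p = 0.041). Mcpt4, a mast cell protease, lay at 37.7 and 17.8 TPM with the antibody against 13.8 and 17.6 TPM with IgG in set 076, and Fcer1a, the IgE receptor chain, at 3.68 and 3.09 TPM against 1.25 and 2.50 TPM. For neutrophils, 8 of 9 members were higher (median 0.28, adjusted p = 2.3e-07, but 0.556 with an estimated correlation). The neutrophil medians were 0.25 in set 076 (adjusted p = 0.346) and 0.96 in set 045 (adjusted p = 1.3e-04), and limma-voom with the set as a term did not call the list (adjusted p = 0.095). Ltf and Ngp, proteins of neutrophil granules, lay at 49.3 and 149 on the protein-coding scale in antibody library D2IA of set 076. Ltf was highest in antibody library D1IA of set 045, at 80.1 from 53 reads, where Ngp had no reads. Without D2IA the neutrophil list had adjusted p = 0.885, and without D1IA of set 076 the red cell and mast cell lists had adjusted p = 0.252 and 0.194. The ranges over all alternatives were 1.2e-17 to 0.998 for red cells, 6.8e-09 to 0.999 for mast cells and 1.1e-15 to 0.998 for neutrophils.

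The remaining lists called higher were those of cartilage and bone, heart muscle, mitochondrially encoded genes and brown fat, each with adjusted p = 0.999 with an estimated correlation. The cartilage and bone list had 9 of 16 members higher (median log2 fold change 0.04, camera adjusted p = 5.2e-05). Col10a1, a collagen of hypertrophic cartilage, lay at 27.9 TPM in D1IA and 8.40 TPM in G1IA of set 076, and Col2a1, the main cartilage collagen, at 22.5 and 11.4 TPM. The heart muscle list had 11 of 11 members higher (median 0.19, adjusted p = 2.8e-04). With the protein-coding scale and the set as a term 2 of 13 were higher and 11 lower (median -0.44, adjusted p = 0.255), and its median was -1.45 in set 045 (adjusted p = 0.029) and 0.66 in set 076 (adjusted p = 0.053). In set 045 the mean log2 value of the list stood at 3.93 in IgG library C1IA and at 1.27 in C2IA, 0.93 in D1IA and 1.25 in D2IA, so the fall there rested on C1IA. Nppa, the atrial peptide hormone, lay at 64.2 TPM in IgG library G1IA and 59.7 TPM in antibody library D1IA, and Sln, a regulator of calcium uptake in the atrium, at 14.4 and 15.5 TPM. The mitochondrially encoded list had 13 of 13 members higher (median 0.16, adjusted p = 3.4e-04), with medians of 1.27 in set 045 (adjusted p = 4.4e-06) and -0.11 in set 076 (adjusted p = 0.601). mt-Nd3 and mt-Co3 had log2 fold changes of 0.28 and 0.24. The brown fat list was called higher (adjusted p = 0.027) although its median was -0.23, with 6 members higher and 8 lower. Elovl3 and Dio2, genes of heat-producing fat, lay at 1.11 and 7.64 TPM in IgG library G1IA and at 16.9 to 32.6 and 31.8 to 42.4 TPM in the other 3 libraries of set 076. Without D1IA of set 076 the cartilage and bone, heart muscle and brown fat lists all turned to lower, with adjusted p = 0.781, 0.036 and 0.301. The calls were also lost without C2IA of set 045 for cartilage and bone (0.224), heart muscle (0.692) and mitochondrially encoded genes (0.130), without C1IA for the last (0.083), without D1IA of set 076 for it as well (0.087), without G2IA for heart muscle (0.148), and for brown fat without C1IA, C2IA, G1IA and D2IA of set 076 (0.641, 0.062, 0.241 and 0.110). The ranges over all alternatives were 5.0e-15 to 0.999, 8.2e-21 to 0.999 and 9.0e-12 to 0.999, and 1.1e-13 to 0.999 for the mitochondrially encoded list.

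Macrophages and contractile smooth muscle, main cell types of the plaque and its wall, were not called over all 8 libraries in TPM. Of 24 tested macrophage genes, 1 was higher and 23 lower (median log2 fold change -0.14, camera adjusted p = 0.867, with the test pointing up). Fcgr3, an Fc receptor, lay at 82.7 and 52.0 TPM with IgG against 49.2 and 62.7 TPM with the antibody in set 076. Cx3cr1, the fractalkine receptor, lay at 3.76 and 1.38 TPM against 0.913 and 3.22 TPM. The macrophage medians were 0.55 in set 045 (adjusted p = 1.1e-07) and -0.25 in set 076 (adjusted p = 0.053), and the difference between the sets had an adjusted p of 9.6e-07, but 0.584 with an estimated correlation. On the protein-coding scale with the set as a term the macrophage list was called higher (21 members higher and 3 lower, adjusted p = 0.0012, but 0.710 with an estimated correlation), and without G1IA it was called higher in TPM (adjusted p = 0.0195). It was also called higher with median-of-ratios scaling (7.7e-04), quantile normalization (0.0040), array weights (3.8e-06) and limma-voom with the set as a term (0.0022, but 0.702 with an estimated correlation), within a range of 1.1e-07 to 0.999 over all alternatives. The contractile smooth muscle list had 5 of 25 members higher and 20 lower (median -0.16, adjusted p = 0.380, with the test pointing up), and 16 higher and 9 lower on the protein-coding scale with the set as a term (median 0.06, adjusted p = 0.122). Its medians were 0.12 in set 045, where it was called higher (adjusted p = 0.0132), and -0.14 in set 076 (adjusted p = 0.114). The difference between the sets had an adjusted p of 0.0106, but 0.584 with an estimated correlation. In TPM it was called higher without D1IA or D2IA of set 045, G1IA or G2IA (adjusted p = 0.0194, 0.0043, 5.4e-05 and 5.8e-04) and lower without D1IA of set 076 (adjusted p = 0.034), within a range of 5.4e-05 to 0.999 over all alternatives. Des, an intermediate filament protein, and Sost, a Wnt inhibitor, had the smallest p in it, with log2 fold changes of 0.43 and 0.46. In all, 10 lists were called higher, 1 lower and 25 not called, with a smallest adjusted p of 0.0930 among the last. fry called 0 lists (smallest adjusted p = 0.998). An interaction of treatment and set passed for 0 of 18170 genes in limma, with 924 at an unadjusted p under 0.05, and for 19 of 37 lists with the preset correlation but 0 with an estimated correlation (smallest adjusted p = 0.325).

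**Figure D4:**
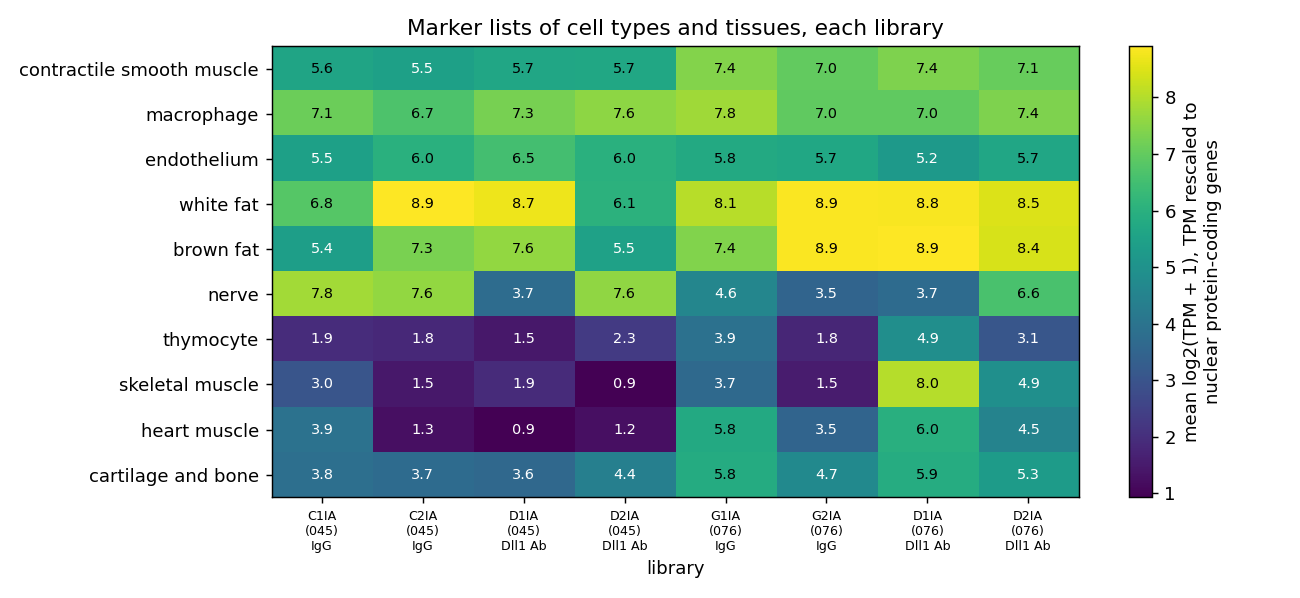
Mean log2(TPM + 1) on the protein-coding scale of the members of 10 marker lists (lines of the grid) in each of the 8 libraries (columns, with set and treatment), with the value printed in each cell and shown by colour. The skeletal muscle list stands at 8.03 in antibody library D1IA of set 076 and at 0.94 to 4.89 in the other 7 libraries.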

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

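Of the tests given here, those of V segment sharing, T cells, fat, the treatment, 7SL RNA, smooth muscle share and skeletal muscle were chosen only after the results they bear on were seen.

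In 12 cases 1 library stood apart from the other 3 of its group, by a gap above Dixon's 95% critical value for the ratio of gap to range in log2(TPM + 1). 150 groups were tested, and chance would give about 7.5 such cases if the 4 libraries of a group were alike. Each group held 2 libraries of each set, and genes lay a median of 2.17 higher in set 076 on the log2 scale. The number expected by chance is therefore no sound measure here. All 12 lay in libraries of set 076, the set with the higher levels. IgG library G1IA stood above the other IgG libraries for Pvalb (0.999), Myh4 (2.12), Tnnc2 (1.36), Cd8b1 (2.51), Dntt (2.80), Nppa (6.03) and Pth (0.20, from 1 read). Antibody library D1IA stood above the other antibody libraries for Igkv1-135 (1.35), Iglc3 (0.83), Igkv4-53 (0.31) and Ighv1-82 (1.24). These rest on only 7, 4, 1 and 6 reads. D1IA also held Pth, parathyroid hormone, at 7.65, or 200 TPM, where the other 3 antibody libraries lay at 0.304 TPM or less.

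The first pattern was the split of the libraries into sets 045 and 076. 7SL RNA alone, diluting every gene alike, would leave few genes apart on the protein-coding scale, but 9.52% of genes were still called there (1729 genes). GC content and transcript length, known for 99.7% of genes, accounted for 13.6% of the variance of the gene differences between sets. This was under the share set beforehand for a main cause. The differences had a Spearman correlation of -0.318 with GC content and -0.168 with length. Counting error adds variance that neither could explain, and its size was not measured, so a part of both stays open. A lower share of smooth muscle with all other cell types raised alike was tested by the medians of 7 other cell type lists. These lay 4.78 apart on the log2 scale, with skeletal muscle at 2.66 and nerve at -2.13. T cells lay at 1.27 and white fat at 0.93. The macrophage, endothelial and fibroblast lists lay closer together, at 0.00060, -0.33 and 0.58. The explanation is thus argued against for skeletal muscle and nerve, which lie beside the artery, but not for these last 3 lists. The labels give no group that follows the sets, so no other biological explanation was tested, and library preparation and dissection stay open.

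The second pattern was the lower level of immunoglobulin and plasma cell genes with the antibody. Reads moved among near-identical V segments are argued against by Ighm, Igkc, Jchain, Mzb1 and Tnfrsf17, whose median log2 fold change in set 076 was -3.68 (SD 0.90 over these genes). The constant gene Igha, not part of that test, went the other way there (log2 fold change 4.23), mostly through D2IA. In set 076 the T cell list had a median of 0.46 and the white fat list of 0.21 (SD 0.72 and 0.32 over their genes, not over libraries). The white fat value argues against less fat on the antibody arteries. The T cell value cannot exclude thymus or T cell rich tissue on the IgG arteries, because such genes lay high in a library of each group. Both values compare 2 libraries with 2. The T cell list had mean log2 values on the protein-coding scale of 3.84 in G1IA and 1.55 in G2IA, against 3.89 and 2.81 with the antibody. The thymocyte list had 3.92 and 1.79 against 4.88 and 3.06. Immunoglobulin did not follow these lists across the libraries. Igkc lay at 4303 in G1IA and 8288 in G2IA on that scale, against 294 and 490 with the antibody. The treatment itself stays open: the mean constant gene share was lower with the antibody in both sets, but in set 045 through C1IA alone (382, with C2IA at 61.6 below both antibody libraries at 185 and 68.2), and the exact permutation p was 0.229. Of the 35 splits of the 8 libraries 8 gave as small a p for the list (smallest other 2.3e-22), so chance cannot be excluded, and tissue with plasma cells carried along with the 2 IgG arteries of set 076 stays open too, since Slpi was lower with the antibody there as well (9.11-fold), while the lymphatic endothelial list was low in D1IA alone (mean 3.80, against 4.89 in D2IA and 5.10 and 4.77 with IgG).

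The third pattern was the higher level of skeletal muscle genes with the antibody in set 076, where set 045 had a median of -0.65 (adjusted p = 0.139). Muscle carried along with D1IA of that set alone stays open: without this library the list was still called higher with the preset correlation (adjusted p = 6.8e-34), but its median fell from 1.69 to 0.49, and it was not called with an estimated correlation (adjusted p = 0.534) or on the protein-coding scale with the set as a term (adjusted p = 0.0624). The median of all genes fell as well without D1IA, from -0.17 to -0.48, so not all of the fall was particular to the list. Muscle in both antibody libraries of the set stays open as well: 17 of 19 tested members were above both IgG libraries in both, just under the bound of 9 in 10 set for the test. An effect of the antibody on muscle genes of the artery cannot be told apart from it in set 076, because both would act on the same 2 libraries. D1IA, which held most of the muscle signal, also held Pth at 932 and Col10a1 at 130 on the protein-coding scale and the highest means of the thymocyte and red cell lists (4.88 and 8.72), which are not muscle genes.

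Other splits of the 8 libraries bear on the counts. limma called 0 genes higher and 0 lower (59 at an unadjusted p under 0.05, and 0 by limma-voom with the set as a term), which all 35 splits reach by construction, so the splits say nothing of these counts. The highest other count was 10915 in either direction, from the split by set, which points to a structure of the samples. With the set as a term 0 genes were higher and 1 was lower. For the 10 lists higher, 17 of 35 splits gave as many (highest other 18), so chance cannot be excluded. Of the 18 splits that put libraries of each set equally on both sides, 4 gave as many (highest other 15) and 4 as small a p for the B cell and plasma cell list (smallest other 2.6e-12), and 18 are too few for a share under 5%. The 1 list lower was reached by 35 of 35 splits (highest other 18), so they say nothing of it.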

How the results depend on the processing

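The alternatives on the protein-coding scale, limma-voom, each set alone, the fit without the 2 libraries with Xist reads and the added tests of the skeletal muscle list without D1IA of set 076 were chosen after seeing the data, and the others were planned. The fits of each set alone and without the libraries with Xist reads were on the protein-coding scale, the last with the set as a term. More than 1 choice thus changed in them against the main test. No paired analysis was possible because the columns of the table do not say which numbered sample of the labels each holds, and the set was used as a term instead. The tools planned for raw counts were not run. For 7 combinations of a gene and a fit the gene had no reads in the libraries used, so no value could be given. Of 1008 values of the 62 genes followed under the alternatives set beforehand 897 kept direction and side of the threshold and 111 reversed. Under added ones 299 of 343 did, 41 reversed and 3 passed the threshold. None of these genes passed in the main test, so none could lose a call. In TPM the set as a term and plain empirical Bayes leave the log2 fold change as it was, so they could reverse no gene. Of 283 values of the 15 lists followed under those set beforehand 187 kept both, 56 lost the call, 8 gained it and 32 reversed. Under added ones 58 of 93 kept both, 17 lost the call, 5 gained it and 13 reversed. Of the counts of genes and lists, 52 of 72 set beforehand and 14 of 24 added stayed within 1.5 times. The cause was not tested for any change given here, except that fits on 1 set or without a library hold fewer samples. Depth limits set 045 most, since its library D1IA holds 663099 protein-coding reads.

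The count of genes called higher by limma was 0 under every alternative (limma-voom included), and the count called lower was 0 under all but 2, against 59 genes at an unadjusted p under 0.05 in the main comparison. With the set as a term 1 gene was lower, and in set 076 alone on the protein-coding scale 3 were. Against 10 lists higher and 1 lower, 4 were higher with no filter, 1 with an estimated correlation and 0 with fry. On the protein-coding scale 17 were higher both without and with the set as a term, and 17 in set 045 alone. The lists lower were 2 at a pseudocount of 0.1 TPM, with median-of-ratios scaling, with quantile normalization, with plain empirical Bayes, on the protein-coding scale without and with the set as a term and with limma-voom. They were 5 with array weights, and 0 with an estimated correlation and with fry. On the protein-coding scale they were 8 in set 076 alone and 3 in set 045 alone. On that scale with the set as a term they were 0 without the libraries with Xist reads, against 2 with all 8 libraries. Leaving out 1 library gave 4 lists higher (without D1IA of set 076) to 17 (without G1IA), and 1 to 5 lower (5 without D1IA of set 076).

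Log2 fold changes reversed as follows. At a pseudocount of 0.1 TPM Nrarp had -0.071 and Nppa -0.056. With median-of-ratios scaling Notch1 had 0.028, Notch2 0.11, Jag1 0.046 and Nppa -0.075. With quantile normalization Dll1 had 0.054, Notch1 0.044, Notch2 0.12, Jag1 0.054 and Nppa -0.076. With array weights the muscle genes Myh1, Tnnc2 and Mylpf had -0.032, -0.019 and -0.11, and the Notch genes Notch4, Dll4, Hey1 and Nrarp -0.0016, -0.31, -0.14 and -0.27. Tcf7, Cd8b1 and Trbc1 of T cells had -0.21, -0.084 and -0.23, and Ltf and Ngp of neutrophils -0.11 and -0.19. Col10a1 and Col2a1 had -0.15 and -0.15, Nppa and Sln -0.52 and -0.29, Fcer1a and Mcpt4 -0.094 and -0.41, Elovl3 and Dio2 -0.18 and -0.35, and Sost and Des -0.0063 and -0.66. On the protein-coding scale, without and with the set as a term alike, Dll1 had 0.11, Notch2 0.11, Jag1 0.031, Tcf7 -0.077, Nppa -0.73 and Sln -0.33. With limma-voom Notch1 had 0.058, Notch2 0.21 and Jag1 0.061. In set 076 alone Jag2 had 0.67 and mt-Co3 -0.013. In set 045 alone Myh1, Tnnc2, Mybpc1 and Mylpf had -2.33, -1.74, -1.62 and -1.38, and Iglv2 2.43. Dll1, Notch1, Notch2, Notch3, Jag1 and Heyl had 0.78, 0.25, 0.37, 0.037, 0.27 and 0.067 there. Tcf7, Cd8b1, Ngp, Col2a1, Nppa, Sln, Fcer1a, Fcgr3 and Des had -1.44, -0.70, -0.25, -0.43, -2.91, -1.35, -0.51, 0.091 and -0.30 there. Without the libraries with Xist reads, on the protein-coding scale with the set as a term, Jag2 had 0.47, Nrarp -0.13, Tcf7 -0.11 and Fcer1a -0.79. Of these, Tcf7 was also reversed on that scale with all 8 libraries (-0.077).

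Adjusted p-values of lists whose direction reversed were as follows. For the Notch component list they were 0.827 at a pseudocount of 0.1 TPM, 0.777 with median-of-ratios scaling, 0.667 with quantile normalization, 0.280 with array weights, 0.642 and 0.592 on the protein-coding scale without and with the set as a term, 0.601 with limma-voom and 0.0657 in set 045. For the Notch target list they were 0.963 at a pseudocount of 5 TPM, 0.995 at a mean of 5 TPM, 0.862 with median-of-ratios scaling, 0.999 with the set as a term, 0.997 in set 076, 0.838 without the libraries with Xist reads and 0.998 with fry. For heart muscle they were 0.979 with median-of-ratios scaling, 0.744 with quantile normalization, 0.983 with array weights, 0.458 and 0.255 on the protein-coding scale without and with the set as a term and 0.029 in set 045. For brown fat they were 1.5e-10 with array weights and 0.998 with fry. For macrophages they were 0.855 with no filter, 0.935 at a pseudocount of 5 TPM, 0.053 in set 076 and 0.998 with fry. For contractile smooth muscle they were 0.114 in set 076 and 0.998 with fry. Skeletal muscle had 0.139 in set 045 and mitochondrially encoded genes 0.601 in set 076. Calls were lost with median-of-ratios scaling for T cells (0.262), thymocytes (0.380), cartilage and bone (0.291) and brown fat (0.077), and with quantile normalization for these 4 lists (0.093, 0.135, 0.135 and 0.122) and mitochondrially encoded genes (0.122). With no filter they were lost for T cells (0.314), cartilage and bone (0.308), mast cells (0.308), brown fat (0.808), heart muscle (0.699) and mitochondrially encoded genes (0.675), and with array weights for thymocytes (0.095) and mast cells (0.106). They were also lost for heart muscle at a pseudocount of 0.1 TPM (0.132) and for brown fat and mitochondrially encoded genes at 5 TPM (0.070 and 0.077). With limma-voom they were lost for heart muscle (0.088) and brown fat (0.115). Without the libraries with Xist reads, on the protein-coding scale with the set as a term, they were lost for cartilage and bone (0.117) and heart muscle (0.086). Heart muscle was not called on that scale with the set as a term and all 8 libraries either (0.255). In set 045 alone, on the protein-coding scale, calls were lost for T cells (0.598), thymocytes (0.742), brown fat (0.150) and cartilage and bone (0.066), and in set 076 alone for the last (0.343).

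Leaving out 1 library unbalances the sets, and the median log2 fold change of all genes, -0.17 with 8 libraries, ranged from -0.67 (without D2IA of set 076) to 0.31 (without D1IA of set 045). Leaving out 1 library at a time, the log2 fold change ranged from -0.49 to 0.16 for Dll1, -0.70 to 0.16 for Notch1, -0.85 to 0.40 for Notch2, -0.75 to 0.097 for Notch3, -0.21 to 0.29 for Notch4, -0.39 to 0.31 for Dll4, -0.80 to 0.30 for Jag1 and -0.45 to 0.0998 for Jag2. It ranged from -0.10 to 0.30 for Hey1, -0.91 to 0.21 for Hey2, -0.67 to 0.13 for Heyl, -0.84 (without C1IA) to -0.079 (without D2IA of set 045) for Hes1, -0.38 to 0.45 for Nrarp, -1.18 to 0.24 for Psenen and -0.86 to 0.21 for Itch. Among muscle genes it ranged from 0.79 to 3.11 for Pvalb, 0.69 to 2.69 for Tnni2, 0.69 to 2.50 for Myh1, 0.60 to 2.78 for Myh4 and 0.45 to 2.85 for Mylpf, each lowest without D1IA of set 076. Among immunoglobulin genes it ranged from -3.82 to -1.31 for Ighm, -4.21 to -1.05 for Igkc, -3.76 to -1.20 for Jchain and -1.78 to -0.66 for Mzb1, each lowest without C2IA and highest without G1IA or G2IA. For immune cell genes it ranged from -0.29 to 1.23 for Tcf7, -0.22 to 1.47 for Trbc1, -0.11 to 1.32 for Dntt, -0.049 to 1.05 for Ltf, -0.70 to 1.16 for Ngp, -0.040 to 0.70 for Fcer1a, -0.44 to 0.99 for Mcpt4, -0.63 to 0.090 for Cx3cr1 and -1.15 to 0.56 for Fcgr3. For other genes it ranged from -0.32 to 1.81 for Hba-a1, -0.22 to 1.46 for Col10a1, -0.81 to 1.71 for Nppa, -0.53 to 1.12 for Sln, -0.15 to 0.78 for mt-Nd3, -0.28 to 0.86 for mt-Co3, -0.25 to 1.53 for Dio2, -0.18 to 1.03 for Sost and -0.49 to 1.11 for Des. Adjusted p-values of lists ranged from 0.511 to 0.946 for Notch components, 0.304 to 0.952 for Notch targets, 5.0e-15 to 0.781 for cartilage and bone, 8.2e-21 to 0.692 for heart muscle and 9.0e-12 to 0.641 for brown fat. The macrophage list ranged from 0.0195 (higher, without G1IA) to 0.971. The contractile smooth muscle list ranged from 5.4e-05 (higher, without G1IA) to 0.641, and was called lower without D1IA of set 076 (adjusted p = 0.034).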

Other observations

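The tests within sets, between sets and of shared V segments were chosen only after the results were seen, and the list tests over all 8 libraries were planned. Nerve genes ranged widely among the libraries of each group. The mean log2(TPM + 1) of the nerve, Schwann cell and ganglion list on the protein-coding scale was 7.80 and 7.61 in IgG libraries C1IA and C2IA and 3.75 and 7.59 in antibody libraries D1IA and D2IA of set 045. In set 076 it was 4.59 and 3.50 with IgG and 3.74 and 6.61 with the antibody. The list was not called between the treatments (median log2 fold change -0.15, camera adjusted p = 0.998). Its median was -2.17 in set 045 (adjusted p = 0.0146), where D1IA alone lay low, and 1.42 in set 076 (adjusted p = 0.105), and the difference between the sets had an adjusted p of 0.0015 with the preset and 0.715 with an estimated correlation. Sterol synthesis genes, which make cholesterol, had a mean of 7.35 and 6.56 with IgG against 4.62 and 6.11 with the antibody in set 045, and of 4.34 and 4.02 against 4.05 and 5.98 in set 076. Their median log2 fold change was -1.64 in set 045 (adjusted p = 2.9e-07) and 0.91 in set 076 (adjusted p = 1.9e-04), and the difference between the sets had an adjusted p of 8.8e-10 with the preset and 0.584 with an estimated correlation.

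Genes of modulated smooth muscle, of which 15 of 21 are also in another list, had a median log2 fold change of 0.72 in set 045 (adjusted p = 1.2e-07) and -0.39 in set 076 (adjusted p = 3.7e-05). The endothelial list had 0.54 (adjusted p = 8.8e-07) and -0.30 (adjusted p = 1.4e-05). For the differences between the sets the adjusted p was 8.8e-10 and 5.3e-09, but 0.325 and 0.584 with an estimated correlation. Over all 8 libraries neither list was called in TPM (adjusted p = 0.979 for both), but on the protein-coding scale with the set as a term both were called higher (adjusted p = 0.0168 for both, and 0.710 with an estimated correlation). With limma-voom the adjusted p was 0.0064 for modulated smooth muscle (but 0.677 with an estimated correlation) and 0.330 for endothelium.

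The IgG libraries of set 076 shared V segments. G1IA held 54 and G2IA 72 segments with at least 10 reads, out of 167 with any read, and 40 were in both where 23.3 would be expected from independent lists (Fisher's exact p = 4.1e-08). The antibody libraries D1IA and D2IA of the set held 11 and 16, with 2 in both where 1.1 would be expected (Fisher's exact p = 0.284). IgG library G2IA shared 11 segments with D2IA where 6.9 would be expected and 8 with D1IA where 4.7 would be (Fisher's exact p = 0.036 and 0.057), and G1IA shared 7 and 4 with them where 5.2 and 3.6 would be (Fisher's exact p = 0.399 and 0.748). After Benjamini-Hochberg adjustment over the 6 pairs of libraries of set 076 the p was 2.5e-07 for the IgG pair and 0.107 or more for the other 5. The shared count was above the expected one in all 6 pairs. Reads of variable segments numbered 8693 and 11300 in the IgG libraries but 407 and 933 in the antibody libraries. The other pairs thus had less power, and the sharing cannot be called particular to the IgG pair. Segments with more germline use or similar sequence can raise such an overlap, and this was not tested. Reads of T cell receptor constant genes per 1000000 protein-coding reads were 39.2 and 5.12 with IgG and 73.0 and 13.8 with the antibody in set 076. Rag1, which joins antigen receptor segments in immature lymphocytes, lay at 13.7 TPM in G1IA, 0.297 TPM in G2IA, 21.1 TPM in D1IA and 5.45 TPM in D2IA of set 076.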
